A study of Homo sapiens with 2 samples.

How the data were processed

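Cardiomyocytes differentiated from the human induced pluripotent stem cell line SCVI-111 were compared after replating on day 18 at 181000 cells per cm2 (Dense) or 33000 cells per cm2 (Sparse) and collection on day 20, with 1 library of 3′ single-cell RNA sequencing per density. The deposited values were unfiltered counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger 3.1.0 on GRCh38, per the file headers and the submitters' processing notes, which also name bcl2fastq without a version. The release of the gene annotation is not stated in these sources. Each table held 33538 genes and 6794880 barcodes, and 33456 gene identifiers were found in GENCODE release 29, which gave the coordinates. There were 22232953 UMIs in Dense and 26365295 in Sparse.

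The groups, gene lists, marker lists, comparisons, rule for named genes and 21 alternatives were fixed before the data were examined. A barcode was kept as a cell with at least 10% of the 99th percentile of UMIs among the top 3000 barcodes of its library (7200.8 UMIs in Dense, 11359.1 in Sparse) and at least 500 genes. Mitochondrial UMIs could be at most the median plus 3 median absolute deviations (MAD) over both libraries, which was 35.85%. Of 282 Dense barcodes, 1 was removed for genes, 101 for mitochondrial UMIs and 4 as Scrublet doublets, leaving 176 cells. Of 263 Sparse barcodes, 18 and 3 were removed for the latter reasons, leaving 242 cells. A median empty droplet (50 to 300 UMIs) held 0.284% of a Dense cell's UMIs and 0.138% of a Sparse cell's, and no background was subtracted.

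Cells of both libraries were clustered together without integration with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 20 principal components, 15 neighbours, resolution 0.5). Genes of the cycle lists, mitochondrially encoded genes and ribosomal protein genes were not used for the clustering. Clusters were named from fixed markers of 11 cell classes. Counts were summed over the cardiomyocyte-like cells of each library and expressed as counts per 10⁶ UMIs (CPM) of all genes. Ratios were log2 of Sparse over Dense with 5 CPM added to each value, for genes of at least 10 CPM in a library. Plain ratios, given without log2 among the results flagged for a closer look, had no CPM added. Genes at least 1.5-fold apart were counted by size alone, without a test. Intervals of 95% were exact Poisson for summed counts and exact binomial for shares of cells and for plain ratios of CPM. The interval of 1 list median in cycle-positive cells came from 200 Poisson draws. All of these hold counting error only, of cells for shares of cells and of UMIs for the others. Those of UMIs leave out the spread between cells, and none holds the spread between libraries. The interval of the ratio of mean G2/M UMIs per cell came instead from 1000 redraws of cells, and holds the spread between cells within each library. For the cycle calls, cells were thinned at random to 26000 UMIs, the 10th percentile of the shallower library's cells rounded down to a multiple of 500 UMIs, and a cell with at least 3 UMIs of 30 cycle genes was positive.

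The rule for named genes took the 12 genes with the largest ratio in each direction among those with at least 50 CPM in a library, leaving out mitochondrially encoded, ribosomal protein and sex-linked marker genes. It added from each fixed list the 2 to 4 measured members with the largest absolute ratio, all measured members of the IGF axis, and IGFBP2, MKI67, TOP2A and TNNT2. The 26 fixed lists covered G1/S, G2/M and cycle call genes, kinase inhibitors and p53 targets, the IGF axis, YAP, Wnt, Notch, and TGF-beta and BMP genes. They also covered sarcomere, calcium, contact, chamber, sinoatrial, hypertrophy, actin and matrix genes, metabolism, hypoxia, cholesterol synthesis, ATF4 and unfolded protein genes, immediate early genes and interferon genes. Another 2 lists, mitochondrially encoded and ribosomal protein genes, described RNA quality. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Of the fixed lists, only H19 of the IGF axis was not in the tables and was not analysed here.

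Some choices were made after the data had been seen. They were the MAD without scaling to a normal distribution (the scaled reading is the 1 added alternative), the range of empty droplets, the expected doublet rate of 1%, and the clustering settings other than the resolution. They also included the naming of a cluster as cardiomyocyte-like, the extra genes shown by cycle state such as CDKN1A, the values of CDKN1A and COL1A2 without the cell of most UMIs, and the counting band from 200 Poisson draws by which values under alternatives were called moved. Calling and ratios were tested on simulated data. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.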

Results

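Human induced pluripotent stem cells of the line SCVI-111 had been differentiated into cardiomyocytes by modulation of Wnt signalling. On day 18 the cells were replated at 181000 cells per cm2 (Dense) or at 33000 cells per cm2 (Sparse), and on day 20 each culture was dissociated and its RNA was counted cell by cell from the 3′ ends of transcripts. The culture medium held insulin and a compound written CHI99021, read here as the GSK3 inhibitor of nearly that name, which activates Wnt signalling. There was 1 library per density, so no difference had a replicate check and no test across samples was possible. Every value describes these libraries. Unless stated otherwise, the ranges in parentheses are 95% intervals of counting error only, exact Poisson for summed molecules and exact binomial for shares of cells. Those of summed molecules leave out the spread between cells. The Dense library held 22232953 unique molecular identifiers (UMIs, each marking a captured RNA molecule) and the Sparse library 26365295. After filtering, 176 Dense cells with 8994335 UMIs and 242 Sparse cells with 17896457 UMIs remained. A Dense cell had a median of 46453 UMIs, 6938 detected genes and 17.6% mitochondrial UMIs, and a Sparse cell had 66043 UMIs, 8059 genes and 12.7%.

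The retained cells of both libraries were cardiomyocyte-like. In each of the 5 clusters, all 12 cardiomyocyte markers had a UMI in at least 50% of cells, and TNNT2, cardiac troponin T of the thin filament, had a UMI in 100% of cells. Summed over cells, TNNT2 stood at 9417 counts per 10⁶ UMIs (CPM; 9354–9481) in Dense and 9197 CPM (9153–9242) in Sparse. The endothelial gene CDH5, the fibroblast genes LUM and DCN and the leukocyte gene PTPRC had no UMI in either library, and PECAM1 had 1 UMI, in Sparse. ACTA2 and TAGLN, used as smooth muscle markers, had UMIs in 95.5% and 87.5% of Dense cells and in 98.3% and 95.5% of Sparse cells, so they did not mark a separate population. Some markers of other classes were as widespread in Dense and Sparse cells: endothelial KDR (90.3% and 92.6%), fibroblast COL1A1 (85.2% and 92.6%) and epicardial KRT19 (89.2% and 93.8%). Single Dense cells held 146 of 165 COL1A2 UMIs and all 56 UMIs of the neural marker STMN2, so lone cells of another type are not excluded. The clusters were split nearly by library: cluster 1 held 5 Dense and 107 Sparse cells, cluster 2 held 109 and 0, cluster 3 held 0 and 78, cluster 4 held 56 and 5, and cluster 5 held 6 and 52. All comparisons within the cardiomyocyte-like class therefore set clusters 2 and 4 of Dense mainly against clusters 1, 3 and 5 of Sparse.

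The first question, named in the title of the series, was how IGFBP2 differed between the densities. IGFBP2 encodes a secreted protein that binds insulin-like growth factors (IGFs), and it lies on chromosome 2 at 216632828–216664436, plus strand (GRCh38, GENCODE release 29). It was higher in Sparse, at 222.8 CPM (215.9–229.8; 3987 UMIs), than in Dense, at 114.2 CPM (107.3–121.4; 1027 UMIs). The log2 ratio of Sparse over Dense, with 5 CPM added to each value as for all log2 ratios here unless stated, was 0.93. In cells thinned to 26000 UMIs, an IGFBP2 UMI was found in 93.4% of 229 Sparse cells (89.4–96.3) and in 80.5% of 159 Dense cells (73.5–86.4), and the order was the same without thinning. No cluster of another cell type was present to show the background, but an empty droplet held only 0.139% of a Sparse cell's IGFBP2 UMIs and 0.397% of a Dense cell's. The difference was present both in cycle-positive cells, which held at least 3 UMIs of 30 cycle genes after thinning, at 229.1 CPM (220.1–238.3) against 131.8 CPM (122.8–141.2), and in cycle-negative cells, which held fewer, at 208.7 CPM (198.0–219.8) against 77.0 CPM (66.8–88.4).

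Other members of the IGF axis differed in both directions. Of its 13 measured members, 5 were at least 1.5-fold higher in Sparse, 2 were at least 1.5-fold higher in Dense and 6 were within 1.5-fold. With 20 CPM added, 2 were higher in Sparse by that margin. The list's median log2 ratio was 0.37, at the 99.96th percentile of 10000 random lists of the same size matched on mean expression, which describes these libraries only. Besides IGFBP2, the members higher in Sparse were the binding proteins IGFBP3 (37.2 against 14.8 CPM, log2 ratio 1.09) and IGFBP4 (38.7 against 22.5 CPM, 0.67), the glycoprotein gene STC2 (15.9 against 6.67 CPM, 0.84) and the receptor adaptor IRS2 (13.5 against 5.89 CPM, 0.76). Those higher in Dense were IGFBP5, at 397.4 CPM (384.4–410.6) against 242.1 CPM (235.0–249.4) and a log2 ratio of -0.70, and the insulin receptor INSR, at 58.0 against 34.9 CPM and -0.66. IGFBP7 (log2 ratio 0.37), IRS1 (0.46), IGF2R (0.17) and the IGF receptor IGF1R (-0.19) were within 1.5-fold, as were PAPPA, at 9.89 CPM in Sparse and 10.0 CPM in Dense, and IGFBP6, at 47.8 and 48.1 CPM. IGF2 was listed at 0 UMIs in both libraries, which allows at most 0.410 CPM in Dense and 0.206 CPM in Sparse. The gene overlaps the readthrough gene INS-IGF2 on the same strand, so its reads could have been left uncounted and its level is uncertain.

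**Figure D1:**
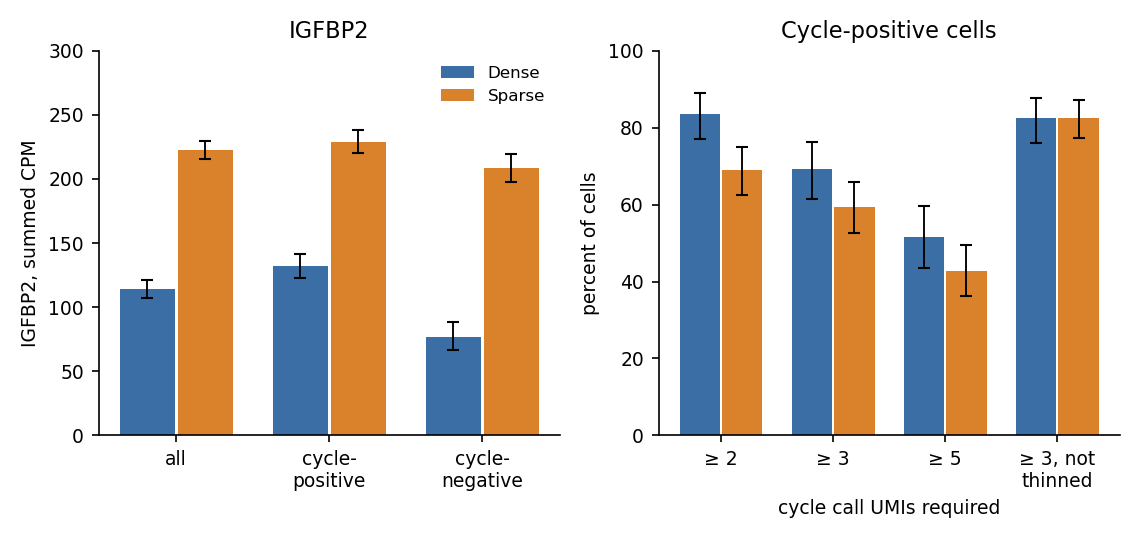
Left, IGFBP2 in CPM summed over all, cycle-positive and cycle-negative cardiomyocyte-like cells; right, the percent of cells called cycle-positive at 26000 UMIs per cell with at least 2, 3 or 5 UMIs of 30 cycle genes, and with 3 UMIs without thinning. Bars are the Dense and Sparse libraries. Error bars are exact 95% intervals of counting error, of UMIs on the left and of cells on the right. IGFBP2 is higher in Sparse in each part. The lower cycle-positive share of Sparse at equal depth (59.4% against 69.2%) is absent without thinning (82.6% against 82.4%), where Sparse cells were deeper.

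The second question was how cell-cycle activity differed with density. Transcripts of the division machinery were lower in Sparse as a list. MKI67, a marker of cycling cells on chromosome 10 (128096659–128126385, minus strand), stood at 36.7 CPM (33.9–39.6) in Sparse and 78.7 CPM (73.0–84.7) in Dense, a log2 ratio of -1.01, and the DNA topoisomerase gene TOP2A at 68.8 CPM (65.0–72.7) against 142.5 CPM (134.8–150.6). Of 49 measured G2/M genes, 27 were at least 1.5-fold higher in Dense and none was higher in Sparse by that margin, with a median log2 ratio of -0.62, below all 10000 random lists. The count was 9 of 47 with a mitochondrial limit of 20%, 17 of 48 with no limit and 10 of 49 with 20 CPM added. The centromere and kinetochore genes CENPE (18.8 against 49.1 CPM, log2 ratio -1.19), NDC80 (13.5 against 34.5 CPM, -1.09) and CENPF (69.5 against 152.4 CPM, -1.08) and the mitotic gene GTSE1 (17.1 against 39.9 CPM, -1.02) led that list. The 30 genes used to call cycling cells, several of them shared with the G2/M list, had a median of -0.70, with 25 higher in Dense (5 of 29 with a mitochondrial limit of 20%) and ASPM, a spindle pole gene, at 29.5 against 72.8 CPM.

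DNA replication genes were also lower in Sparse as a list. Of 38 measured G1/S genes, 2 were at least 1.5-fold higher in Dense, RRM2 (log2 ratio -0.70), a subunit of ribonucleotide reductase, and WDR76 (-0.61), and the list's median was -0.27, again below all random lists. The median was smaller in size than that of G2/M genes here but larger with a mitochondrial limit of 20%, at -0.50 with 13 of 39 higher in Dense against -0.36 for G2/M genes, and the difference between the lists was not tested. CASP8AP2 and the helicase gene BLM stood at -0.58 each. With every cell thinned to 26000 UMIs, the mean count of G2/M UMIs per cell was 54.2 in Sparse and 83.4 in Dense and that of G1/S UMIs 45.4 and 53.1. The median counts were 29 and 35 for G2/M, closer than the means, and 24 and 29 for G1/S. At that depth, 136 of 229 Sparse cells were cycle-positive (59.4%, 52.7–65.8) and 110 of 159 Dense cells (69.2%, 61.4–76.3), and these intervals overlapped. Of these cells, 41 Sparse and 39 Dense cells held 2 or 3 UMIs, at the limit or 1 UMI under it, and 13 Sparse and 17 Dense cells were left out as too shallow. With a mitochondrial limit of 20%, which also raised the thinning depth to 31500 UMIs, the shares were 59.9% and 79.2%, a difference of -19.3 points instead of -9.79. Without thinning, which also returned the cells left out as too shallow, 82.6% of Sparse cells and 82.4% of Dense cells were positive. The order was not seen there, but Sparse cells were deeper, at a median of 66043 against 46453 UMIs. The same Sparse cells read 69.0% positive at 60% of their depth, so the unthinned shares do not compare cells at equal depth. In cycle-negative cells, where 15 G2/M genes were measured, the list's median was 0.022 instead of -0.62 and the difference was not seen. These cells were selected for few UMIs of the call genes, several of them shared with the G2/M list. The selection itself favours a missing difference, so this value cannot count against the difference in all cells.

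Inhibitors of cyclin-dependent kinases and targets of p53 went the other way. Of 18 measured members, 7 were at least 1.5-fold higher in Sparse and none was higher in Dense by that margin, with a median log2 ratio of 0.47, above all random lists. The count was 2 of 18 with centred ratios or with 20 CPM added, and 4 of 18 with doublets kept. CDKN1A, the inhibitor p21, stood at 370.5 CPM (361.7–379.5) in Sparse and 161.0 CPM (152.8–169.5) in Dense, a log2 ratio of 1.18, although a single cell held 20.4% of the Dense UMIs and another 8.5% of the Sparse UMIs. GDF15, a stress-induced cytokine, was at 15.5 against 2.89 CPM (log2 ratio 1.38), ZMAT3 at 127.3 against 79.3 CPM (0.65) and FDXR at 27.8 against 15.9 CPM (0.65). CDKN1A was higher in Sparse in cycle-positive cells, at 337.0 against 113.1 CPM, and in cycle-negative cells, at 429.3 against 278.1 CPM, where a single cell held 40.2% of the Dense UMIs and another 18.1% of the Sparse UMIs. Without the cell of most CDKN1A UMIs in each library, the cycle-negative values were 361.9 and 174.7 CPM, and those of all cells 344.0 and 130.0 CPM.

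Across 8965 measured genes, 350 were at least 1.5-fold higher in Sparse and 263 in Dense, and 82 and 67 at least 2-fold. The median log2 ratio of all measured genes was 0.068. Of the genes past 1.5-fold, 57.1% were higher in Sparse, a split that depended on the scaling: it was 45.0% with the ratios centred on their median and 48.7% with mitochondrial and ribosomal protein genes left out of the totals.

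Of the 12 genes with the largest ratios towards Dense, 4 were on the list of the TGF-beta and bone morphogenetic protein (BMP) pathway, ID3, ID1, SMAD6 and ID4. ID3 and ID1, inhibitors of helix-loop-helix transcription factors that BMP signalling induces, had log2 ratios of -4.22 and -4.12. ID3 (chromosome 1, 23557918–23559794, minus strand) stood at 155.0 CPM (147.0–163.3) in Dense and 3.58 CPM (2.75–4.57) in Sparse. ID1 (chromosome 20, 31605283–31606515, plus strand) stood at 85.9 CPM (80.0–92.2) in Dense and 0.224 CPM (0.0609–0.572) in Sparse, from 773 and 4 UMIs. ID4 stood at 151.5 against 35.5 CPM in Dense and Sparse (log2 ratio -1.95) and the inhibitory SMAD6 at 116.1 against 22.7 CPM (-2.13). SMAD9 (59.0 against 8.66 CPM, -2.23), also among the 12, was on no fixed list. Of the 15 measured genes of the TGF-beta and BMP list, 8 were at least 1.5-fold higher in Dense, 1 was higher in Sparse and 6 were within that margin, with a median of -0.84, below all random lists. The ligand gene BMP2 (286.4 against 83.9 CPM, -1.71) and the inhibitory SMAD7 (39.8 against 10.1 CPM, -1.57) were chosen after their values were seen. The ligand gene BMP4 was higher in Sparse, at 13.5 against 3.78 CPM (1.08).

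Immediate early genes, which cells induce within minutes of stimulation or dissociation, were also higher in Dense. Of 18 measured members, 9 were at least 1.5-fold higher in Dense and none in Sparse, with a median of -0.59, below all random lists. FOS stood at 75.6 against 11.6 CPM (log2 ratio -2.28), FOSB at 54.6 against 8.44 CPM (-2.15), EGR1 at 45.0 against 7.88 CPM (-1.96) and JUN at 184.6 against 68.7 CPM (-1.36). The Dense library also had the higher median mitochondrial share (17.6% against 12.7%). The other genes among the 12 with the largest ratios towards Dense were DOK4, an adaptor of receptor tyrosine kinases (182.9 against 27.3 CPM, -2.54), the muscle creatine kinase CKM (141.8 against 22.7 CPM, -2.41), the ventricular myosin light chain MYL2 (158.0 against 34.9 CPM, -2.03), the thioredoxin-binding gene TXNIP (139.9 against 31.7 CPM, -1.98) and G0S2, an inhibitor of lipolysis (83.8 against 20.3 CPM, -1.81).

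The 12 genes with the largest ratios towards Sparse were more varied. FGF12, an intracellular fibroblast growth factor homologue that binds sodium channels, stood at 105.7 CPM in Sparse and 26.2 CPM in Dense, a log2 ratio of 1.83. The metallothionein MT1X followed (59.7 against 13.8 CPM, 1.79), with the caution that metallothionein genes share near-identical sequence. ECEL1, an endopeptidase, stood at 106.1 against 27.2 CPM (1.78) and the surface glycoprotein CD24, which has processed pseudogenes, at 291.5 against 92.7 CPM (1.60). NPPA, atrial natriuretic peptide, stood at 361.1 CPM (352.3–370.0) against 149.0 CPM (141.1–157.2), a ratio of 1.25. AHNAK2 (1.45), the endocytic gene EHD3 (1.42), TMTC4 (1.41), TMEM88 (1.39), the membrane protein gene EMP2 (1.37), the cathepsin gene CTSV (1.22) and LACC1 (59.6 against 23.1 CPM) completed the group.

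**Figure D2:**
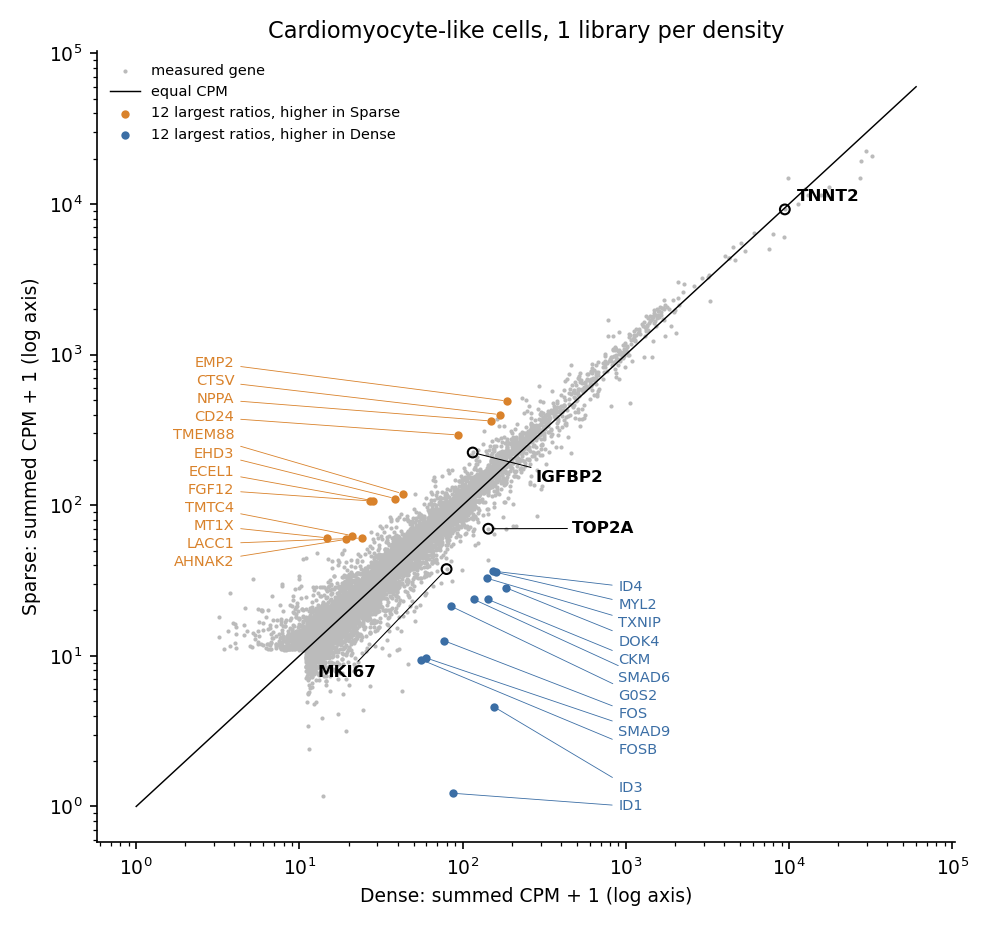
Each point is 1 of 8965 measured genes, placed by its CPM plus 1 in the Dense library (horizontal log axis) and the Sparse library (vertical log axis), with the line of equal values. Coloured points are the 12 genes with the largest ratios in each direction; ID1 and ID3 lie farthest from the line, at 0.224 and 3.58 CPM in Sparse against 85.9 and 155.0 CPM in Dense, and open circles mark IGFBP2, MKI67, TOP2A and TNNT2.

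Sarcomere and ventricular lists had medians lower in Sparse, and the atrial list a median higher in Sparse. Of 27 measured sarcomere genes, 6 were at least 1.5-fold higher in Dense and 1 in Sparse, with a median log2 ratio of -0.21, below all random lists. MYL2, the cardiac troponin I gene TNNI3 (127.1 against 302.4 CPM, -1.22), the titin-capping gene TCAP (133.0 against 305.3 CPM, -1.17) and MYOM2 (3.13 against 16.2 CPM, -1.39) led it, while the atrial light chain MYL7 was higher in Sparse, at 14970 against 9883 CPM (0.60). Of 10 ventricular markers, 2 were at least 1.5-fold higher in Dense (CKM, MYL2) and 2 in Sparse, the peroxiredoxin PRDX1 (1.13) and the transcription factor HEY2 (0.77), with a median of -0.29, at the 0.03rd percentile. Of 6 measured atrial markers, NPPA and MYL7 were at least 1.5-fold higher in Sparse and the alpha myosin heavy chain MYH6 in Dense (5034 against 7576 CPM, -0.59), NR2F2 stood at 0.51, and the median was 0.46, at the 99.88th percentile. The atrial median lay within the central 95% of random lists at minima of 1 CPM (0.24, 94.6th percentile) and 100 CPM (97.2th), and only 1 atrial marker passed 1.5-fold towards Sparse with centred ratios. Of 5 measured sinoatrial markers, TBX3 (-1.31) and the pacemaker channel HCN4 (-0.78) were higher in Dense, BMP4 was higher in Sparse and ISL1 (0.33) was within 1.5-fold. Their median of -0.11 was within the range of random lists, and it was 0.077 without mitochondrial and ribosomal protein genes in the totals. Of 18 genes of calcium handling and ion channels, only HCN4 passed 1.5-fold, and the median of -0.035 changed sign with the minimum CPM. ATP2A2, the calcium pump of the sarcoplasmic reticulum, stood at 1124 against 860.5 CPM (0.38), and the channel genes KCNJ3 and KCNQ1 at 0.41 and -0.46.

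Genes of cell contacts, gave a median within the range of random lists (0.14, 74.2th percentile). Of 21 measured members, 2 were at least 1.5-fold higher in Sparse and none in Dense. Both were gap junction genes: GJA5, connexin 40, at 28.9 CPM (26.5–31.5) against 6.78 CPM (5.19–8.71), a log2 ratio of 1.52, and GJA1, connexin 43, at 28.2 CPM (25.8–30.7) against 9.23 CPM (7.35–11.4), a ratio of 1.22. GJC1, connexin 45, had a ratio of -0.48 and JUP, plakoglobin, of 0.52. The targets of YAP and TEAD, effectors of the contact-sensitive Hippo pathway, had a median of 0.14 (87.4th percentile). Of 15 measured, IGFBP3 and CCDC80 (0.80) were at least 1.5-fold higher in Sparse, ANKRD1 (221.1 against 462.7 CPM, -1.05) and CYR61 (27.0 against 46.5 CPM, -0.69) in Dense.

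The medians of the stretch and actin lists were lower in Sparse, with most members within 1.5-fold. Of 13 hypertrophy and stretch genes, ANKRD1, the skeletal actin ACTA1 (-0.94) and FHL1 (-0.71) were at least 1.5-fold higher in Dense and NPPA in Sparse, with a median of -0.35, below all random lists. That count in Dense was 1 with no mitochondrial limit, against 2 in Sparse, 1 with 20 CPM added and 5 by the mean of per-cell CPM. Of 21 actin and SRF target genes, CNN1 (-0.73) and FHL1 were at least 1.5-fold higher in Dense, ACTG1 and CNN2 stood at -0.39 and 0.39, and the median was -0.21, also below all random lists. With no mitochondrial limit, no actin gene passed 1.5-fold. Of 17 extracellular matrix genes, COL5A2 (154.9 against 73.6 CPM, 1.02) and SPARC (213.6 against 110.3 CPM, 0.92) were higher in Sparse and COL1A2 and the laminin LAMA4 (-0.65) in Dense, with a median of 0.15 (70.1th percentile). The matrix median was -0.13 (0.14th percentile) in cycle-negative cells, outside the central 95% of random lists, and 0.070 (3.96th) with no mitochondrial limit. For COL1A2, 146 of the 165 Dense UMIs came from a single cell, so its ratio of -1.70 describes that cell. Without the cell of most COL1A2 UMIs in each library the ratio was -0.14, at 1.47 against 2.15 CPM.

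Cholesterol synthesis genes were higher in Sparse. Of 19 measured members, 11 were at least 1.5-fold higher in Sparse (6 with 20 CPM added) and 1 in Dense, with a median log2 ratio of 0.67, above all random lists. MSMO1 stood at 80.1 against 35.6 CPM (1.07), ACAT2 at 61.9 against 30.5 CPM (0.92) and HMGCS1 at 111.0 against 58.3 CPM (0.88), whereas SC5D, chosen after its values were seen, was higher in Dense, at 68.6 against 35.5 CPM (-0.86). Genes of the ATF4 and unfolded protein responses had a median of 0.33, above all random lists, with the amino acid transporter SLC7A5 (23.9 against 5.78 CPM, 1.42) at least 1.5-fold higher in Sparse, ATF3 (-0.63) in Dense and 19 of 21 within that margin, among them CEBPB (0.47) and PSAT1 (0.45). The list no longer stood outside the central 95% of random lists without a mitochondrial limit (0.29, 95.4th percentile), in cycle-negative cells (0.19, 90.8th) or at a minimum of 100 CPM (0.19, 75.4th).

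Of 17 glycolysis genes, ALDOC (82.0 against 34.8 CPM, 1.13) was at least 1.5-fold higher in Sparse and the glucose transporter SLC2A3 (-0.60) in Dense, with PDK1 and PKM at -0.27 and -0.25. Their median of 0.023 was at the 5.84th percentile, and it was -0.038 without mitochondrial and ribosomal protein genes in the totals and -0.044 with centred ratios. Of 32 nuclear genes of oxidative phosphorylation, COX6A2 (18.2 against 34.7 CPM, -0.78) alone passed 1.5-fold, and the median was 0.19 (83.2th percentile). None of 16 fatty acid oxidation genes passed 1.5-fold, and their median was -0.12, at the 0.32nd percentile, with ACADVL at -0.56 and CPT1A at -0.50. Of 11 hypoxia targets, ADM (19.2 against 34.7 CPM, -0.72) passed 1.5-fold, P4HA2 stood at 0.57, KDM3A at -0.49 and VEGFA at -0.36, with a median of -0.14, at the 2.02nd percentile. The list lay within the central 95% of random lists with doublets kept (2.90), 1 CPM added (2.90), the empty-droplet profile subtracted (3.23) or a minimum of 1 CPM (2.78).

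Of the remaining pathways, none of 10 measured Wnt targets passed 1.5-fold. CCND1, cyclin D1, stood at 115.2 against 157.2 CPM (-0.43), AXIN2 at 16.7 against 11.3 CPM (0.41), LEF1 at 0.40 and TCF7 at -0.25. Their median was 0.012 (23.6th percentile), and it was -0.12 without mitochondrial and ribosomal protein genes in the totals. Of 9 Notch pathway genes, HEY2 was at least 1.5-fold higher in Sparse, with JAG1 at 0.56, NOTCH1 at 0.41, NOTCH3 at 0.23 and a median of 0.15 (86.9th percentile). Of 8 interferon and antigen presentation genes, PSMB9 (-0.63) was at least 1.5-fold higher in Dense, with IFI6 at 0.52, IFITM3 at 0.48 and a median of 0.14 (78.1th percentile).

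As lists of RNA quality, the 13 mitochondrially encoded genes had 4 at least 1.5-fold higher in Dense, 9 within that margin and a median of -0.43, below all random lists. MT-ND6 stood at -1.03, MT-CO3 at -0.87 and MT-CO1 at -0.64. Of 82 ribosomal protein genes, 5 were at least 1.5-fold higher in Sparse and none in Dense, with a median of 0.24 (99.96th percentile). RPL36A (1.16), RPS27L (1.07) and RPL17 (1.04) led that list, and ribosomal protein genes have many processed pseudogenes, which leaves their counts uncertain.

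**Figure D3:**
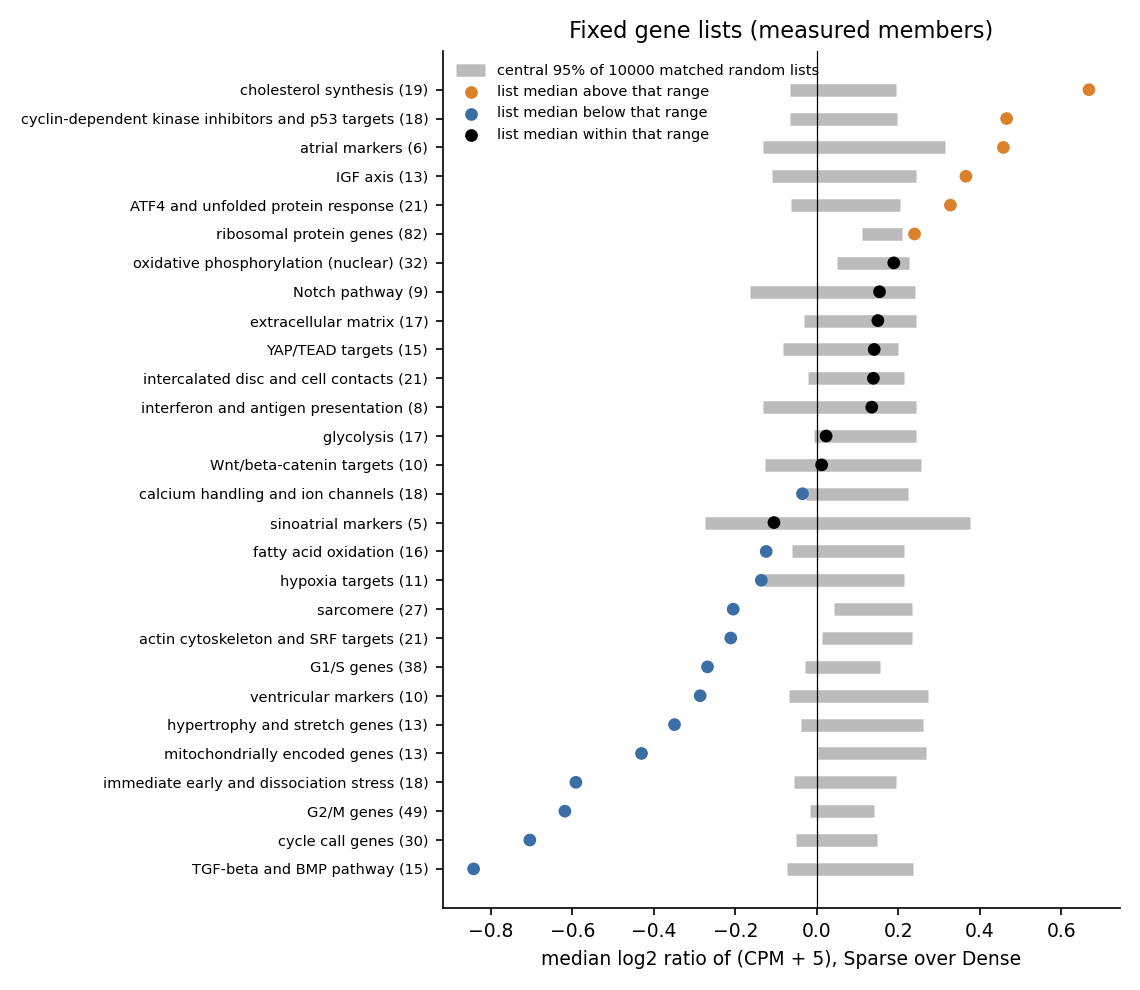
Median log2 ratio of Sparse over Dense, with 5 CPM added, for the 28 fixed gene lists (measured members in parentheses); grey bars are the central 95% of 10000 random lists of the same size matched on mean expression. Of the 28 medians, 6 lie above that range, led by cholesterol synthesis at 0.67, and 13 below it, led by TGF-beta and BMP genes at -0.84.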

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

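In this part, the test of ID1 and ID3 in cells without any of 4 immediate early transcripts was written before its value was seen, and all other tests were chosen only after the result was seen.

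A signal outside the report's comparisons came from barcodes above the mitochondrial limit. They were 35.9% of Dense barcodes (30.3–41.9) and 6.8% of Sparse barcodes (4.1–10.6). Among nuclear-encoded UMIs, ID1 stood at 56.1 CPM (41.1–74.8) and ID3 at 58.5 CPM (43.2–77.6) in the removed Dense barcodes, against 103.4 and 186.4 CPM in the Dense cells kept, and both had 0 UMIs in the 18 removed Sparse barcodes. IGFBP2 stood at 250.8 CPM (183.0–335.6) in the removed Sparse barcodes and 134.1 CPM (110.2–161.7) in the removed Dense barcodes. CDKN1A stood at 61.0 CPM (45.3–80.4) in the removed Dense and 66.9 CPM (34.6–116.8; 12 UMIs) in the removed Sparse barcodes, against 193.6 and 420.0 CPM in the cells kept. The CDKN1A difference was not seen there, although the wide Sparse interval leaves a difference possible. FOS stood at 274.4 CPM in the removed Dense barcodes and 90.9 CPM in the Dense cells kept, whereas ID1 and ID3 were lower in the removed. The removed Dense barcodes had medians of 16445 UMIs and 51.9% mitochondrial UMIs, and TNNT2 was lower in them too (8320 against 11330 CPM). They therefore cannot decide whether ID1 and ID3 follow FOS. MKI67 (148.8 against 94.7 CPM) and TOP2A (287.8 against 171.4 CPM) were also higher in the removed than in the kept Dense barcodes. In Sparse, MKI67 stood at 100.3 CPM (59.5–158.6) in the removed and 41.55 CPM in the kept. TOP2A in Sparse stood at 117.1 CPM (72.5–178.9) against 78.0 CPM, which its interval does not separate.

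G2/M genes were lower in Sparse. The mitochondrial limit alone is argued against, since the list's median was -0.504 with no limit and -0.363 at a limit of 20%, although it was smaller there. Depth is argued against by a ratio of mean G2/M UMIs per cell of 0.65 (0.5–0.835) at 26000 UMIs per cell. This interval came from 1000 redraws of cells and holds the spread between cells within each library, not that between libraries. A lower share of cycling cells in Sparse cannot be told apart: among cycle-positive cells the 25 G2/M genes outside the call list had a median of -0.337 (-0.409 to -0.285), but only 48.2% of those Dense cells and 36.8% of those Sparse cells held an MKI67 UMI, so the class is not shown to hold cycling cells alone. Density and any other difference between the libraries, such as handling at dissociation, stay open, and 1 library per density cannot separate them.

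ID1 and ID3 were higher in Dense. Free RNA is argued against, since an empty droplet held 0.4625% of a Dense cell's ID1 UMIs and 0.5114% of its ID3 UMIs. Mitochondrial content is argued against by cells of 10 to 20% mitochondrial UMIs. There the Dense over Sparse ratios, without 5 CPM added, were 825.2 (147.3–32670) for ID1 and 41.5 (29.8–59.4) for ID3. The size of the ID1 ratio is uncertain, since all Sparse cells together held 4 ID1 UMIs. Only 2 Dense cells lacked UMIs of FOS, FOSB, EGR1 and JUN, and both held ID1 and ID3 (100%, lower limit 15.8%). That limit lay above the upper limit of 4.2% of Sparse cells for ID1 but under that of 26.3% for ID3. Since 85.8% of all Dense cells held ID1, finding it in 2 of 2 cells was likely with or without a dissociation response. These 2 cells therefore cannot decide on such a response for either gene. A further test took the 44 thinned Dense cells without a FOS UMI, of which 77.3% (62.2–88.5) held ID1 and 95.5% (84.5–99.4) held ID3, against 0.9% (0.1–3.1) and 7.9% (4.7–12.1) of Sparse cells. It argues against a response read from FOS alone, although absence of a FOS UMI at that depth does not show absence of a response, and density and library stay open.

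IGFBP2 was higher in Sparse. The share of cells called cycle-positive is argued against by Sparse over Dense ratios, without 5 CPM added, of 1.739 (1.605–1.885) in cycle-positive and 2.709 (2.337–3.154) in cycle-negative cells. Of the cycle-negative cells, 2.0% in Dense and 2.2% in Sparse held an MKI67 UMI, but MKI67 is a call gene, so the selection itself keeps that share low. Neither class is shown to be pure, so the ratios speak to the called share only. Mitochondrial content is argued against by a ratio, also without 5 CPM added, of 1.847 (1.679–2.033) in cells of 10 to 20% mitochondrial UMIs. Free RNA is argued against by an empty droplet that held 0.1394% of a Sparse cell's IGFBP2 UMIs. Density and any other difference between the libraries stay open.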

How the results depend on the processing

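All tests of the processing were planned except the mitochondrial limit from the scaled MAD (median absolute deviation), chosen after the distribution had been seen. No paired analysis was possible because each density had 1 library, so the groups shared only replicate number 1 and no test was made. With 1 library per density, no alternative separates density from differences between libraries. Intervals of summed counts, of their ratios and of the list median hold counting error of UMIs alone, without the spread between cells. Those of shares of cells hold the counting error of cells. The interval of the ratio of mean G2/M UMIs per cell came from redraws of cells. None holds the spread between libraries. Depth limited the cycle calls: Sparse cells read 82.6% positive at full and 69.0% at 60% of their depth, and 40.9% and 38.8% after thinning to 13000 UMIs. In simulated counts, 7 of 50 genes with a true 1.5-fold difference were called, 48 of 50 at 2-fold and 0 of 8579 unchanged genes, so a count of genes past 1.5-fold misses most true differences of that size. The simulated counts held Poisson counting error alone, without spread between cells or between libraries. They therefore cannot show how many of the genes counted here differ for such reasons. Of 200 random lists of unchanged genes, 13 lay outside the central 95%.

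IGFBP2 was higher in Sparse under every alternative run for it, with log2 ratios from 0.855 with a pseudocount of 20 CPM to 1.381 in cycle-negative cells. All cells kept were cardiomyocyte-like under every alternative run. The thinning depth followed the cells kept, so shares under the cell filters hold both choices at once. The cycle-positive share was lower in Sparse under each alternative except counting without thinning. Of 496 list medians under the alternatives, 389 were not labelled moved by the counting band, 103 moved and 4 reversed. A list median counted as reversed only if it changed sign and had lain outside the central 95% of random lists, and a gene only if its ratio had passed 1.5-fold. Medians that had lain within that range changed sign as well: sinoatrial and glycolysis in 4 alternatives each, Wnt in 6, and matrix in cycle-negative cells (-0.13). Of 2026 ratios of 127 named genes, 1702 were not labelled moved, 320 moved and 4 reversed, all 4 in cycle-negative cells: MKI67 0.099, RRM2 0.389, CENPE 0.074 and GTSE1 0.054. The G2/M list reversed there too (0.022). Cycle-negative cells were selected for few UMIs of the call genes, which include MKI67, CENPE and GTSE1 but not RRM2. The selection itself keeps these call genes low in both libraries (MKI67 at 1.17 CPM in Sparse and 0.759 CPM in Dense). Their reversals there cannot be read as a difference. The calcium list reversed by the mean of per-cell CPM (0.019) and at minima of 1 CPM (0.052) and 100 CPM (0.10). The cause was not tested for any of these reversals, nor for the moved values that follow, except that a higher minimum CPM leaves fewer genes, a pseudocount shrinks or widens ratios and centring shifts them all alike.

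With a mitochondrial limit of 20% and thinning therefore to 31500 UMIs, 106 Dense cells were called, 79.2% of Dense cells were cycle-positive and the difference in that share was -19.3 points. List medians that moved there were G1/S -0.50, G2/M -0.36, cycle call -0.39, BMP -0.96, matrix 0.097, glycolysis -0.043, oxidative phosphorylation 0.069, cholesterol 0.55, immediate early -0.71, interferon 0.017, ribosomal 0.15 and mitochondrial -0.22. With no mitochondrial limit and thinning therefore to 12500 UMIs, 271 Dense cells were called, 47.5% of Dense cells were cycle-positive, 40% of Sparse cells were cycle-positive and 544 genes were 1.5-fold higher in Sparse. Moved list medians were G1/S -0.14, G2/M -0.50, cycle call -0.62, IGF axis 0.50, calcium -0.092, contacts 0.21, ventricular -0.23, actin -0.12, matrix 0.070, glycolysis 0.18, oxidative phosphorylation 0.36, fatty acid oxidation -0.031, cholesterol 0.73, ribosomal 0.45 and mitochondrial -0.80. With a fixed minimum of 1000 UMIs per cell and thinning therefore to the same 1000 UMIs, 357 Dense cells were called, 17.6% of Dense cells were cycle-positive and 8.87% of Sparse cells were cycle-positive. Among list medians, those that moved were G1/S -0.22, G2/M -0.69, oxidative phosphorylation 0.21, ribosomal 0.27 and mitochondrial -0.46. With doublets kept, the list medians that moved were p53 0.42 and ribosomal 0.25. With a pseudocount of 1 CPM, the list medians that moved were G2/M -0.73, cycle call -0.82, p53 0.56 and cholesterol 0.76. With a pseudocount of 20 CPM, 149 genes were 1.5-fold higher in Sparse and 99 genes were 1.5-fold higher in Dense. List medians that moved there were G1/S -0.19, G2/M -0.38, cycle call -0.48, p53 0.36, cholesterol 0.47, ATF4 0.21 and immediate early -0.41. Without mitochondrial and ribosomal protein genes in the totals, the list medians that moved were G2/M -0.70, cycle call -0.79, Wnt -0.12, sarcomere -0.27, ventricular -0.35, sinoatrial 0.077, actin -0.27, matrix 0.090, glycolysis -0.038 and oxidative phosphorylation 0.13. With ratios centred on their median, the list medians that moved were G1/S -0.34, G2/M -0.69, p53 0.40, sarcomere -0.27, calcium -0.10, contacts 0.072, ventricular -0.35, actin -0.28, matrix 0.082, glycolysis -0.044, oxidative phosphorylation 0.12, ribosomal 0.17 and mitochondrial -0.50. After subtraction of the empty-droplet profile at 10%, the list medians that moved were cycle call -0.65, oxidative phosphorylation 0.24, ribosomal 0.28 and mitochondrial -0.47. By the mean of per-cell CPM, the list medians that moved were G1/S -0.19, IGF axis 0.47, YAP 0.22, sarcomere -0.17, calcium 0.019, ribosomal 0.22 and mitochondrial -0.33. In cycle-negative cells alone, the IGFBP2 log2 ratio was 1.38. Moved list medians were G1/S -0.14, G2/M 0.022, p53 0.35, Wnt 0.13, BMP -0.95, sinoatrial 0.31, matrix -0.13, oxidative phosphorylation 0.15, cholesterol 0.76, ATF4 0.19, ribosomal 0.26 and mitochondrial -0.37. At a minimum of 1 CPM, the list medians that moved were BMP -0.69, calcium 0.052, atrial 0.24 and sinoatrial 0.11. At a minimum of 100 CPM, 92 genes were 1.5-fold higher in Sparse, 54 genes were 1.5-fold higher in Dense and 11 lists lay outside the range of random lists. Among list medians, those that moved were G2/M -0.68, p53 0.62, Wnt -0.22, BMP -1.46, calcium 0.10, ventricular -0.43, ATF4 0.19 and mitochondrial -0.44. With 2 or more cycle UMIs, 83.6% of Dense cells were cycle-positive and 69.0% of Sparse cells were cycle-positive. With 5 or more cycle UMIs, 51.6% of Dense cells were cycle-positive and 42.8% of Sparse cells were cycle-positive. Without thinning and with the shallow cells returned, 82.4% of Dense cells were cycle-positive, 82.6% of Sparse cells were cycle-positive and the difference in that share was 0.258 points. With the mitochondrial limit from the scaled MAD and thinning therefore to 18500 UMIs, 54.7% of Dense cells were cycle-positive and 44.6% of Sparse cells were cycle-positive. List medians that moved there were cycle call -0.66, oxidative phosphorylation 0.22, ribosomal 0.28 and mitochondrial -0.49. Counts past 1.5-fold within lists depended on the alternative too, and some examples follow. G1/S genes higher in Dense were 8 of 38 with 1 CPM added, 7 of 41 without mitochondrial and ribosomal protein genes and 6 of 38 with centred ratios, against 2 of 38. The kinase inhibitor and p53 list had 4 of 18 higher in Sparse at the fixed minimum and 3 of 19 in cycle-negative cells. With no mitochondrial limit, 12 of 82 ribosomal and 9 of 13 mitochondrial genes passed, against 5 and 4. Ventricular genes higher in Dense were 4 of 10 with centred ratios or without mitochondrial and ribosomal protein genes, against 2. Hypertrophy genes higher in Dense were 1 of 13 with no mitochondrial limit or 20 CPM added and 5 by the mean of per-cell CPM, against 3. ATF4 genes higher in Sparse were 3 of 21 with 1 CPM added, against 1, and YAP targets higher in Dense 4 of 16 in cycle-negative cells, against 2.

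Lists that no longer lay outside the central 95% of random lists were calcium (in 6 alternatives), hypoxia (in 4), ATF4 (in 3) and atrial (in 2) lists, G2/M in cycle-negative cells, and G1/S, IGF axis and fatty acid oxidation at 100 CPM. YAP targets lay outside the central 95% by the mean of per-cell CPM, and matrix genes in cycle-negative cells. The quality lists have no value without mitochondrial and ribosomal protein genes, and the cycle call list has none in cycle-negative cells or at 100 CPM. The Notch, sinoatrial, hypoxia and interferon lists have none at 100 CPM, since too few members remained.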

Other observations

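The test of place in the cycle was written before its value was seen, and the other values in this part were chosen after the data had been seen.

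The clusters led by cell-cycle genes differed in their leading genes. Genes of the G1/S, G2/M and cycle call lists were not used to form the clusters, so other genes separated them. Cell-cycle genes outside those lists, such as TK1 and MAD2L1, were not left out. Cluster 4, with 56 Dense and 5 Sparse cells, was led by mitotic genes, among them ASPM, TOP2A, CENPF and MKI67. Cluster 3, with 0 Dense and 78 Sparse cells, was led by UBE2C, a ubiquitin-conjugating enzyme of mitosis, with MAD2L1, a spindle checkpoint gene, and by the replication genes PCNA, TK1 and CDC6. Set against 176 Dense and 242 Sparse cells in all, clusters 3 and 4 did not hold a lower share of Sparse than of Dense cells. Membership of these clusters was not a planned measure of cycling. Cluster 5, with 6 Dense and 52 Sparse cells, was led by FBXO2, UCHL1, GPX3 and PRDX1.

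A hypothesis was that cycle-positive Sparse cells may lie earlier in the cycle than cycle-positive Dense cells. More G1/S than G2/M UMIs were held by 60 of 136 cycle-positive Sparse cells (44.1%, 35.6–52.9) and by 38 of 110 Dense cells (34.5%, 25.7–44.2). By the bound as first written, a Sparse share at or below 44.2% counted against the hypothesis. That bound was set aside after the value was seen, because the share's own interval reaches past it, and the shares were not separated. The lists differ in baseline: at the 10th percentile of thinned Sparse cells they held 18 G2/M and 11 G1/S UMIs. The class was also called on genes shared in part with the G2/M list and is not shown to hold cycling cells alone. The share is therefore not a direct measure of place in the cycle.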
